A study of Homo sapiens with 19 samples.

How the data were processed

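RNA from 19 NB4 cultures was measured on single-colour arrays, 4 each of EV, RA, MycD with RA and MycA with RA and 3 of AraC with RA, grouped by their titles. Per the labels, 500 ng of total RNA was copied with a T7-oligo-dT primer and transcribed into Cy3-labelled cRNA, so signal comes mainly from near the 3′ ends of polyadenylated transcripts. The series design speaks of 4 biologically independent experiments, and the description labels carry 4 experiment numbers. Each number occurs once in every group, except that the AraC group lacks number 1. The arrays lay on 7 slides, per the file headers, and were scanned on 1 day.

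The deposited intensity values were made with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09, probe coordinates on hg19), per the file headers and, for the software's name, per the submitters' processing notes. The processed intensity had been background-subtracted with spatial detrending, detrended multiplicatively and given surrogate values at dim spots, per the file headers, with no scaling between arrays. Spot mean and local background intensity were deposited in the same files. The authors' deposited value table holds log2 values with the same quantiles in every column (medians 7.51), and their ranks within an array matched the spot mean minus the local background (rank correlation 1). Which background step and log transformation made it is not given in the sources used here, and it served only as an alternative. All of its columns were matched to a sample.

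The main values were log2 of the processed signal minus each array's 75th percentile, over 43118 non-control spots. Spots of a probe were averaged, which left 34127 probes, 33867 of them with a value on every array. The probe with the highest mean stood for its gene (26614 genes), and a gene was tested if that probe was well above background on every array of at least 1 group (19763 genes). Gene names came from the files, updated through a RefSeq table of GRCh38.p14 by accession, which matched 24910 probes and 15051 of the tested genes. That table's coordinates were not used, and no genome was used here. RARB, which was to be named in any case, was not among the tested genes.

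Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in a fit of 5 group means over all 19 arrays with 14 residual and 2.36 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Pooling the groups lets the AraC arrays share the estimate of spread. For 22 gene lists fixed in advance (477 genes listed, 470 on the array, 440 tested) limma's camera was run with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 22 lists within each of 5 comparisons. With slide or experiment number as a block, camera was run with the preset correlation only. Single values were compared with exact permutation tests. The share of the RA response took genes called with at least a 2-fold change on 2 EV and 2 RA arrays and measured them on the remaining arrays. A minimum of 5 genes per split was set while that calculation was written, not in advance. Tables were read with the data.table package (1.17.8) and plots drawn with matplotlib 3.10.9.

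The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have come after. The rule named, per comparison, the 6 largest rises and 6 largest falls among called genes with a proper symbol whose groups of arrays did not overlap, up to 3 called members of each list, and always MYC, CYP26A1, RARB, DHRS3, CEBPE, ITGAM and CDKN1A. Members of a list were left out for length after values were seen, mostly from the smallest change up, and all of them in the comparisons against EV. Some other genes that the rule named are not reported. Alternatives were quantile and median scaling, normexp background correction with an offset of 50, the authors' deposited table, other probe filters, the mean of a gene's probes, only the groups compared, array weights, a trended robust prior, a 2-fold minimum, blocks for slide, experiment number and title number, and leaving out each array. Added after seeing the data were scaling to 4 spike-in probes (later also for the share of the RA response), subtracted background plus 50 and a fit without the AraC arrays.

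The steps were tested on simulated data with the real arrays' spread and 67 genes changed at each size, over 10 runs of 19763 genes. Changes of 1.5-fold, 2-fold and 4-fold were recovered for 19.0%, 54.9% and 86.9% of genes for RA against EV. The shares were 17.9%, 54.3% and 87.2% for MycD against RA, 19.4%, 57.6% and 87.2% for MycA against RA, 14.0%, 49.7% and 84.9% for AraC against RA, and 20.1%, 51.6% and 88.7% between the Myc forms. Of 19562 unchanged genes at most 3.7 per run were called on average. In simulated data for AraC against RA, camera found a G2/M list shifted by 0.5 log2 in 10 of 10 runs under both settings, but with the preset correlation it also called a mean of 6.7 of 21 unshifted lists, against 0 with the estimated correlation. The AraC arrays kept their own deviations in these simulations. Those deviations cancel within a gene, so the simulated AraC mean had no sampling error. The simulated AraC recovery, false calls and camera results may therefore be too favourable, and the lower signal of these arrays was not simulated. A simulated share of 0.6 of the RA response was recovered as 0.571 on average (0.421 to 0.623, 5 runs).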

Results

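Gene expression was measured in NB4 cells, a human acute promyelocytic leukaemia line that matures towards neutrophils when given retinoic acid (RA), the ligand of the retinoic acid receptors. The cells carried a retroviral vector that the labels call ER-tagged and that was either empty (EV) or held a form of the transcription factor Myc. The series title calls the MycD form phosphomimetic, and the labels do not say what MycA is. All cultures stood for 16 hours in 200 nM 4-OHT (4-hydroxytamoxifen, an oestrogen receptor ligand used to switch on ER fusion proteins). In 1 group of empty-vector cultures the medium also held 25 µM cytosine arabinoside (AraC), a nucleoside drug that blocks DNA synthesis. RA was then given at 10 nM for 4 hours to every group but EV. Each sample was hybridised to its own single-colour Agilent array, giving 4 EV, 4 RA, 4 MycD with RA, 4 MycA with RA and 3 AraC with RA arrays.

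The array signal was alike in 4 groups and lower in the AraC group. The 75th percentile of the processed signal was 1784 ± 289 in EV, 1900.1 ± 111 in RA, 1966 ± 189 in MycD with RA and 1842 ± 293 in MycA with RA (SD, n = 4 each), against 508 ± 123 in AraC with RA (SD, n = 3). The share of spots well above background was 75.8% ± 1.63 in EV, 75.7% ± 1.94 in RA, 77.8% ± 2.76 in MycD with RA, 76.6% ± 4.27 in MycA with RA and 68.1% ± 1.80 in AraC with RA. Control RNA spiked into each labelling went the other way, with a mean log2 signal of 11.43 ± 0.08 on the RA arrays and 12.57 ± 0.20 on the AraC arrays, 2.21-fold brighter (exact permutation p = 0.0286, two-sided, n = 4 and 3). Relative to those spike-ins, the 75th percentile was 8.42-fold lower with AraC than with RA alone (log2 -3.07, exact permutation p = 0.0286, the smallest that 4 against 3 arrays allow). This ratio, and each value scaled to the spike-ins, assumes that every labelling held the same amount of spike-in, which was not measured separately. Against all 16 other arrays the same difference was log2 -3.02 (exact permutation p = 0.00103, two-sided and again the smallest possible). Changes below are relative to each array's 75th percentile unless stated. The p-values measure the spread between these cultures and arrays, and the number of arrays limits the precision.

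**Figure D1:**
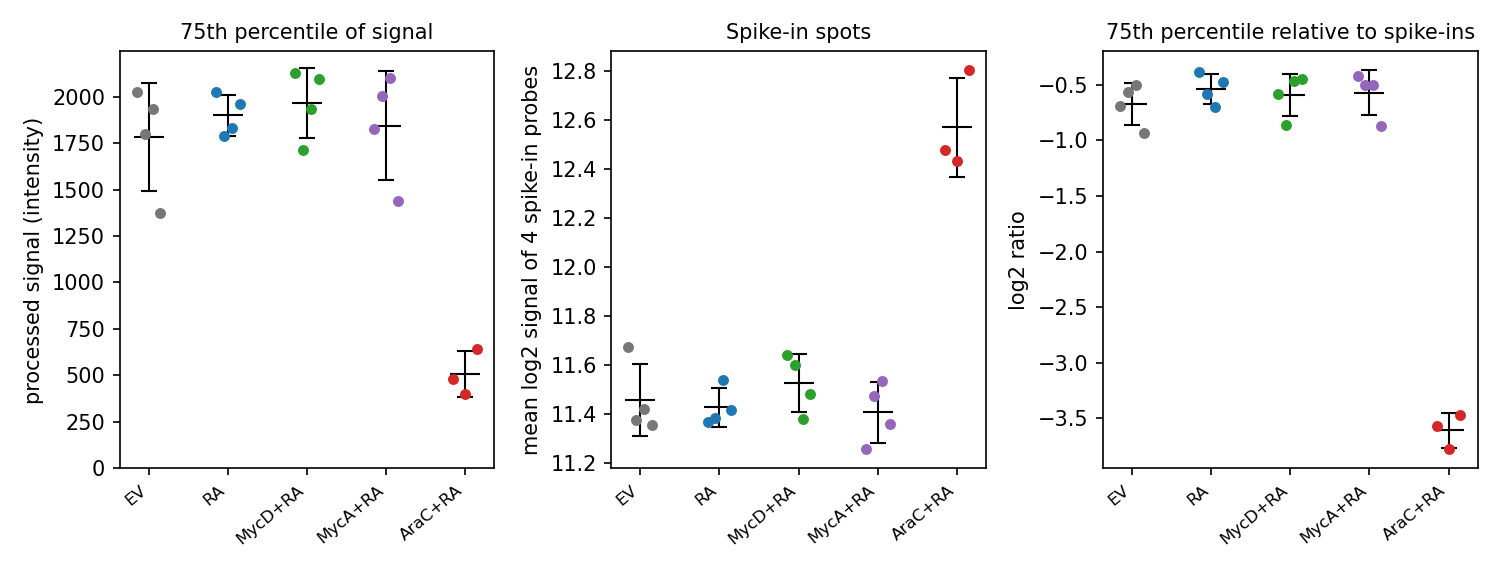
Each dot is 1 array of the 5 groups, each bar a group mean and each whisker its SD. The left panel plots the 75th percentile of processed signal (intensity), the middle panel the mean log2 signal of 4 spike-in probes and the right panel their log2 ratio, where the AraC with RA arrays lie at -3.61 on average and the group means of the others between -0.67 and -0.53.

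The first comparison asks what 4 hours of RA did to empty-vector cells. RA raised ID1, an inhibitor of helix-loop-helix transcription factors, 157-fold (log2 7.29, SE 0.14, n = 4 and 4, limma adjusted p = 1.84e-15). ANGPTL4, a regulator of lipoprotein lipase, rose 122-fold (adjusted p = 1.92e-10), DHRS3, a retinaldehyde reductase, 56.2-fold (adjusted p = 2.67e-12), and the transcriptional repressor gene HIC1 38.4-fold (adjusted p = 4.85e-12). The transglutaminase gene TGM2 rose 88.4-fold (adjusted p = 2.92e-08) on a probe that was above background on 1 of 4 EV arrays, and its other probe rose by log2 4.48. RHBDL3 was not well above background on any EV array and was at least 25.6-fold higher with RA (adjusted p = 1.71e-09). Such a bound sets the mean of the brighter group against the dimmer group's mean of, per array, the larger of the probe's own signal and the lowest signal that was well above background. The largest falls were RAB7B (7.30-fold lower, adjusted p = 1.5e-09), NOG, a secreted BMP antagonist (6.59-fold), the insulin receptor substrate gene IRS1 (6.50-fold), STYK1 (5.48-fold) and FAM43A (5.04-fold). TGFBI, not well above background with RA, was at least 2.53-fold lower (adjusted p = 0.000164), but this call ended when background was subtracted and 50 added (chosen after seeing the data), and its direction turned under normexp.

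Some genes of retinoid handling and of maturation were called as well. Of 18 tested retinoid metabolism and receptor genes 9 rose, 1 fell and 8 did not pass (10 rose and 1 fell adjusted over the list alone), with a median log2 change of 1.11. CYP26A1, which degrades RA, rose 9.77-fold (log2 3.29, SE 0.29, adjusted p = 6e-07). Of 23 genes fixed as RA-responsive in acute promyelocytic leukaemia cells 14 rose, 1 fell and 8 did not pass (14 and 1 adjusted over the list alone), with a median of 2.12. Among them ASB2 rose 17.1-fold (adjusted p = 1.67e-10), the adhesion molecule gene ICAM1 12.2-fold (adjusted p = 2.81e-05), ID2 4.79-fold (adjusted p = 4.18e-08) and CEBPE, a transcription factor of granulocyte maturation, 2.24-fold (adjusted p = 0.00051). Of 18 mature neutrophil genes 6 rose, 0 fell and 12 did not pass (6 and 0 adjusted over the list alone). NCF1, a subunit of the phagocyte oxidase, rose by log2 4.46 (adjusted p = 4.53e-11), PADI4 was at least 7.35-fold higher (adjusted p = 1.38e-09) and the integrin gene ITGAM rose 1.75-fold (adjusted p = 0.000769). The limma camera test with a preset correlation gave adjusted p-values of 6.4e-16, 3.41e-27 and 5.09e-07 for these 3 lists. With an estimated correlation the first 2 held (adjusted p = 0.00621 and 0.00859) and the neutrophil list did not (adjusted p = 0.0551). With slide as a block the medians were 0.93, 2.08 and 0.24 (camera with the preset correlation, adjusted p = 6.33e-14, 2.36e-21 and 4.29e-06). Within the 2 slides that held both groups they were 0.93 and 1.18, 1.42 and 2.21, and for neutrophil genes -0.04 and 0.46.

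**Figure D2:**
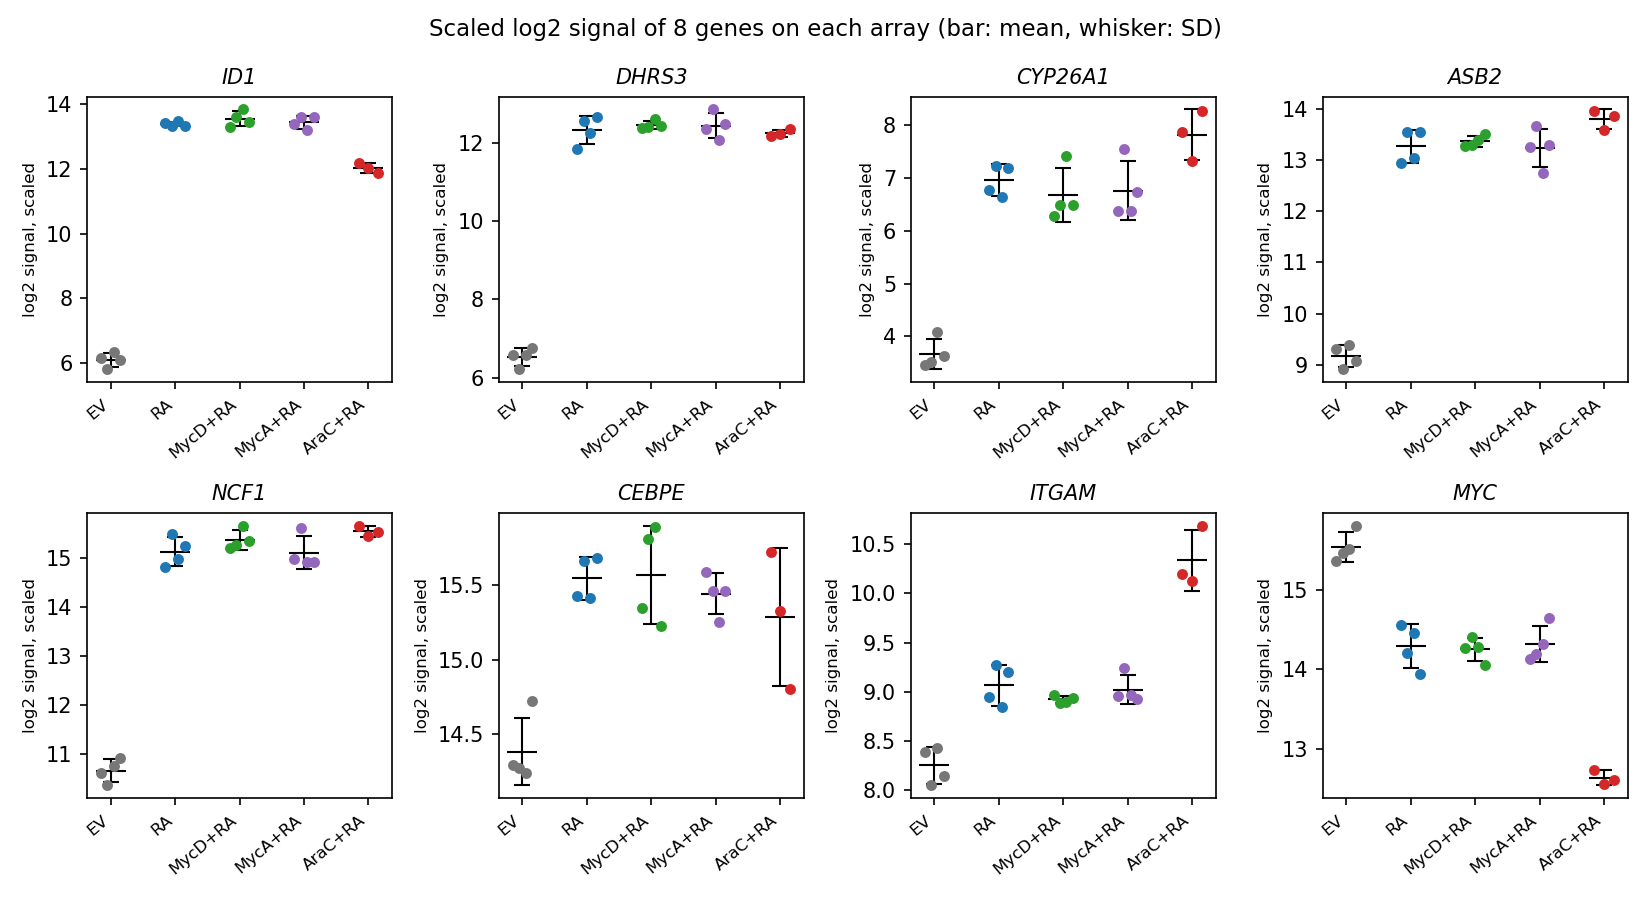
Scaled log2 signal of 8 genes on each array of the 5 groups, with the group mean as a bar and the SD as a whisker. ID1, DHRS3, CYP26A1, ASB2 and NCF1 were low on the EV arrays and high on the RA arrays, with ID1 at a mean of 6.10 and 13.39, while MYC stood at 15.54 and 14.29.

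MYC fell 2.38-fold with RA (log2 -1.25, SE 0.15, adjusted p = 1.73e-05), read by a probe at chromosome 8, 128753268 to 128753327 in hg19. Of 12 MYC network genes 1 rose, 3 fell and 8 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.127). Of 39 MYC-activated genes 0 rose, 4 fell and 35 did not pass (0 and 4 adjusted over the list alone), among them the telomerase gene TERT (1.94-fold lower, adjusted p = 0.00461). The median of that list was -0.11 (-0.17 with slide as a block, -0.26 and -0.02 within slides), turned to 0.03 when arrays were scaled to the spike-ins, and had a camera adjusted p of 0.00206 that became an adjusted p of 0.681 with an estimated correlation. Of 19 MYC-repressed genes 3 rose and 3 fell (5 and 4 adjusted over the list alone), with NDRG1 5.19-fold higher (adjusted p = 8.82e-09) and KLF4 2.94-fold lower (adjusted p = 0.000653), and the list did not pass (camera adjusted p = 0.127). CDKN1A, the cell cycle inhibitor p21, had a log2 change of 0.17 (SE 0.36, adjusted p = 0.973).

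The inflammatory and apoptosis lists had calls in both directions. Of 22 NF-kB and inflammatory genes 5 rose and 2 fell (8 and 3 adjusted over the list alone), with BCL3 8.78-fold higher (adjusted p = 1.53e-07). Of 26 apoptosis regulators 4 rose and 3 fell (10 and 4 adjusted over the list alone), with the death receptor gene TNFRSF10B 2.98-fold higher (adjusted p = 0.000113). Their medians were 0.25 and 0.28 (camera adjusted p = 0.00378 and 0.00206, and adjusted p = 0.681 and 0.266 with an estimated correlation), or 0.08 and 0.26 with slide as a block (adjusted p = 0.047 and 0.0116). Within slides they were 0.09 and 0.51, and 0.20 and 0.31. Of 27 G2/M genes only NEK2, a mitotic kinase, rose (1.46-fold, adjusted p = 0.0095), also adjusted over the list alone, and the list's median of 0.12 (0.13 with slide as a block, 0.07 and 0.08 within slides) passed camera at an adjusted p of 0.0089 but had an adjusted p of 0.484 with an estimated correlation. No other list passed camera. Rises and falls, with the numbers adjusted over the list alone in brackets, were 1 and 2 (1 and 2) of 14 primary granule genes, 2 and 0 (2 and 0) of 27 p53 targets, 0 and 0 (0 and 0) of 32 G1/S genes and 0 and 0 (0 and 0) of 20 histone genes. They were 1 and 0 (1 and 0) of 26 interferon response genes, 3 and 2 (3 and 2) of 16 immediate early genes, 1 and 0 (2 and 0) of 12 heat shock genes, 2 and 1 (2 and 1) of 17 unfolded protein response genes and 0 and 0 (0 and 0) of 38 ribosomal protein genes. In the primary granule list the progenitor factor gene MYB fell 2.85-fold (adjusted p = 4.22e-07), while SERPINB1, an inhibitor of neutrophil proteases, rose 2.05-fold (adjusted p = 1.37e-06). Other called members were PLK3 (3.15-fold higher, adjusted p = 1.25e-06), the interferon regulatory factor gene IRF1 (4.71-fold, adjusted p = 4.91e-09), DNAJB1 (1.86-fold, adjusted p = 0.000194) and DDIT3 (log2 1.93, adjusted p = 8.81e-07). EGR3 was 3.98-fold higher (adjusted p = 0.013), with 1 of 4 EV arrays above background, and was not called without EV replicate 4 (adjusted p = 0.0526) or RA replicate 4 (0.0545) or with slide as a block (0.0744), nor in the authors' deposited value table (0.535). Under normexp IRS1, STYK1, KLF4, PADI4 and EGR3 were not called (adjusted p = 0.275, 0.5, 0.712, 0.112 and 0.5), and under median scaling NEK2 was not (adjusted p = 0.0673). Among markers of other blood and stromal cells, 1 rose and 2 fell of 10 monocyte genes, 2 rose of 11 lymphoid genes (2 and 1 fell adjusted over the list alone), 0 of 10 erythroid genes and 0 of 3 fibroblast genes (1 adjusted over the list alone). The lymphoid kinase gene LCK rose 14.8-fold (adjusted p = 4.36e-10) on its brighter probe, while its other probe had a log2 change of -0.07.

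In all, limma called 1255 of 19763 genes, 718 higher and 537 lower, and 520 of them by at least 2-fold (367 higher, 153 lower). Scaling to the spike-ins, which moved the median of all genes by 0.14 log2, called 594 higher and 181 lower. The fit with slide as a block called 592 higher and 365 lower. The RA and EV arrays did not overlap for 1221 of the called genes, and for 2273 of all tested genes against 565 (2.86%) that chance gives.

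The next 2 comparisons ask what MycD and MycA added to RA. CYP27C1, a cytochrome P450 gene, was the only gene limma called in either. It was above background on all 4 RA arrays and on none of the Myc arrays, so it was at least 4.28-fold lower with MycD (adjusted p = 4.39e-08, n = 4 and 4) and at least 4.00-fold lower with MycA (adjusted p = 4.07e-07, n = 4 and 4). The scaled log2 signal of its probe, at chromosome 2, 127941418 to 127941477 in hg19, was 4.42 ± 0.23 in EV, 4.87 ± 0.52 in RA, 1.13 ± 0.19 with MycD and 1.63 ± 0.21 with MycA (SD, n = 4). Its other probe was not well above background on any array. The call held with slide as a block (adjusted p = 0.000224 and 0.00182) but not in the authors' deposited value table (adjusted p = 0.0821 and 0.691), with subtracted background plus 50 (adjusted p = 1 in both) or under normexp (adjusted p = 0.593 and 0.943). Each Myc array lay below each RA array, so also within every slide that held both (at most 1.83 against at least 4.13). At an unadjusted p below 0.05 there were 331 genes with MycD and 175 with MycA, against 988 that chance gives. The groups did not overlap for 226 genes with MycD and 102 with MycA, against 565 that chance gives. Counts this far below chance mean that the tests may be conservative here, and they do not measure the absence of a Myc effect. The cause of the deficit was not tested.

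**Figure D3:**
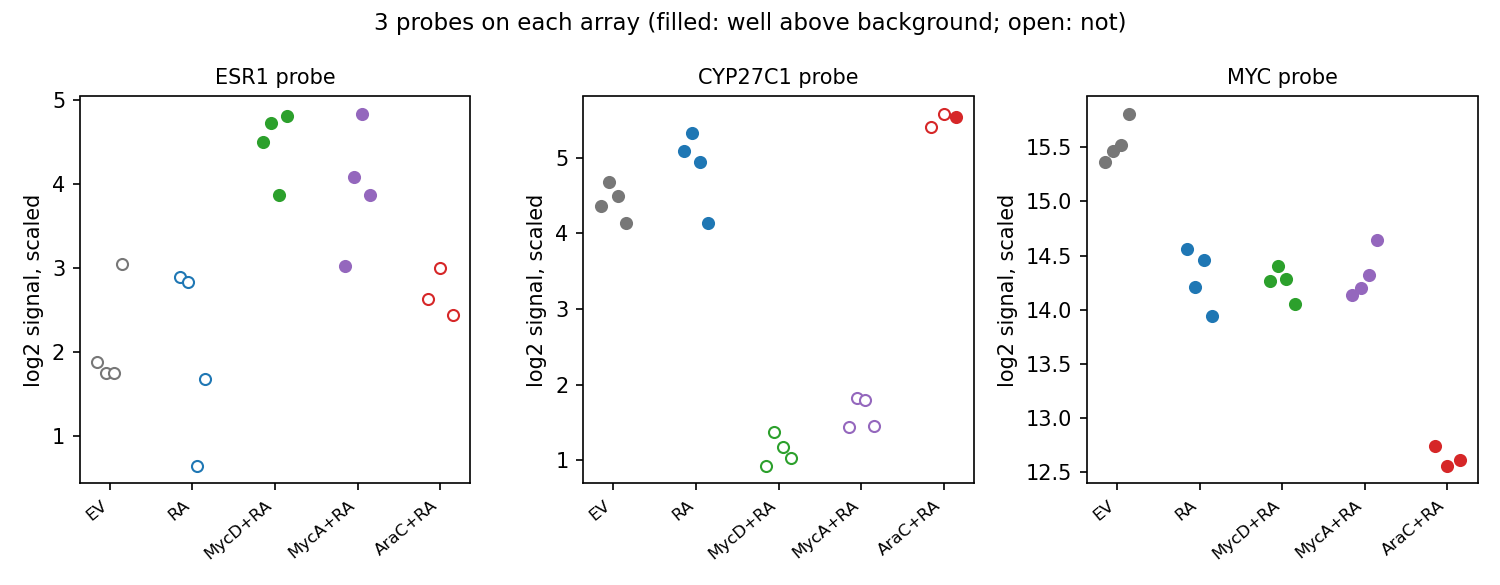
Scaled log2 signal of a probe of ESR1, CYP27C1 and MYC on each array of the 5 groups, with filled dots well above background and open dots not. The CYP27C1 probe averaged 4.87 on the RA arrays and 1.13 and 1.63 on the MycD and MycA arrays, the ESR1 probe 2.02, 4.48 and 3.95, and the MYC probe 14.29, 14.25 and 14.32.

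The other genes named in advance passed in neither comparison. The MYC probe had a log2 change of -0.04 with MycD and 0.03 with MycA (SE 0.15), and whether it also reads MYC made from the vector was not determined. CYP26A1 had -0.29 and -0.20 (SE 0.29), DHRS3 0.14 and 0.11 (SE 0.18), CEBPE 0.02 and -0.11 (SE 0.19), ITGAM -0.14 and -0.04 (SE 0.14) and CDKN1A -0.07 and -0.06 (SE 0.36), all with a limma adjusted p of 1. For 82.0% of genes with MycD and 84.0% with MycA, the 95% interval of the change lay within 2-fold either way, and smaller changes were not excluded.

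Every one of the 22 lists had 0 members called in these comparisons, over all genes and adjusted over the list alone. Camera with the preset correlation nevertheless passed 5 lists for MycD against RA and 0 for MycA against RA. With MycD, 26 interferon response genes had a median log2 change of 0.50 (adjusted p = 7.51e-09) and 22 NF-kB and inflammatory genes 0.41 (adjusted p = 0.000104), and both had an adjusted p of 0.865 with an estimated correlation. With slide as a block these medians were 0.27 and 0.22 (camera again with the preset correlation, adjusted p = 7.8e-05 and 0.00565). Within the 3 slides with both groups they ranged from -0.91 to 1.25 and from -0.52 to 0.91. The other passing lists had small medians of -0.02 for 39 MYC-activated genes (adjusted p = 0.00734), 0.08 for 27 G2/M genes (adjusted p = 0.018) and -0.03 for 38 ribosomal protein genes (adjusted p = 0.018). All 3 had an adjusted p of 0.865 with an estimated correlation. With slide as a block and the preset correlation the values were -0.01 (camera adjusted p = 0.555), 0.08 (adjusted p = 0.0042) and -0.03 (adjusted p = 0.555).

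Between the Myc forms limma called 0 genes, with 274 at an unadjusted p below 0.05, again fewer than the 988 that chance gives. MYC had a log2 difference of -0.07, CYP26A1 -0.08, DHRS3 0.03, CEBPE 0.13, ITGAM -0.10 and CDKN1A -0.01 (MycD minus MycA, adjusted p = 1), and 84.0% of genes had a 95% interval within 2-fold. No list member was called over all genes, and 1 of 22 NF-kB and inflammatory genes was higher with MycD adjusted over the list alone. Interferon response genes were higher with MycD by a median of 0.60 (camera adjusted p = 2.91e-16, and adjusted p = 0.792 with an estimated correlation), or 0.34 with slide as a block and 0.30 within the 1 slide that held both groups. For NF-kB and inflammatory genes the median was 0.40 (camera adjusted p = 1e-05, and adjusted p = 0.792 with an estimated correlation), or 0.08 with slide as a block and -0.11 within that slide. G2/M genes had a median of 0.08 (camera adjusted p = 0.00245, and adjusted p = 0.792 with an estimated correlation), and MYC-activated genes -0.03 (camera adjusted p = 0.0245, and adjusted p = 0.963 with an estimated correlation), or 0.11 and -0.03 with slide as a block (adjusted p = 0.000351 and 0.265).

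The next comparison asks what AraC added to RA. Relative to the rest of the array, AraC raised CDKN1A (log2 3.42, SE 0.39, n = 3 and 4, limma adjusted p = 2.41e-06) and lowered MYC 3.16-fold (log2 -1.66, SE 0.16, adjusted p = 4.49e-07). Several early response and inflammatory genes were higher, among them EGR3 (21.1-fold, adjusted p = 2.91e-06), the chemokine gene CXCL8 (20.2-fold, adjusted p = 3.62e-05), ATF3 (19.1-fold, adjusted p = 6.43e-08) and JUN (13.7-fold, adjusted p = 5.63e-08). Several mitotic genes were lower, among them KIF20A (4.61-fold, adjusted p = 8.24e-09), PLK1 (3.91-fold, adjusted p = 8.28e-08) and CCNB1 (3.20-fold, adjusted p = 8.88e-10). Scaled to the spike-ins, which lowered the median change of all genes by 3.07 log2, CDKN1A had a log2 change of 0.35, MYC -4.73, EGR3 1.33, CXCL8 1.27, ATF3 1.18 and JUN 0.70. All 19763 genes had a median of 0.19 before that scaling and -2.89 after it.

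Among the largest rises were RNF222 (162-fold, adjusted p = 4.33e-07), the organic anion transporter gene SLC22A7 (125-fold), RTL1 (log2 6.60), the RA hydroxylase gene CYP26C1 (89.5-fold, adjusted p = 3.91e-09) and the alcohol dehydrogenase gene ADH1A (65.9-fold). On the RA arrays RTL1 was above background on 1 of 4 and ADH1A on 2, and the other SLC22A7 probe rose by log2 1.5. All 5 stayed higher when scaled to the spike-ins, by log2 4.27, 3.89, 3.53, 3.41 and 2.97. The largest falls were the linker histone genes H1-3 (10.4-fold, adjusted p = 1.87e-08) and H1-5 (6.22-fold, adjusted p = 9.57e-07), the spindle gene PSRC1 (8.73-fold, adjusted p = 4.38e-12), the helicase gene PIF1 (7.25-fold, adjusted p = 6.61e-10) and ACP7 (6.58-fold, adjusted p = 1.12e-05), whose probe was above background on 1 of 3 AraC arrays. PRDM12, not well above background with AraC, was at least 2.81-fold lower (adjusted p = 1.5e-08), a direction that turned with subtracted background plus 50.

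Cell cycle lists moved apart. Of 27 G2/M genes 0 rose, 22 fell and 5 did not pass (1 and 22 adjusted over the list alone), with a median log2 change of -0.84 (-0.88 with slide as a block, -1.09 within the 1 slide with both groups and -3.91 scaled to the spike-ins). It was the only list in this comparison to hold with an estimated correlation (camera adjusted p = 1.12e-11, and 0.0373 with an estimated correlation). Of 32 G1/S and DNA replication genes 17 rose, 1 fell and 14 did not pass, the same adjusted over the list alone, with cyclin E2 (CCNE2) 6.38-fold higher (adjusted p = 4.57e-10) and E2F2 4.05-fold higher (adjusted p = 2.66e-09). That list's median was 0.32 (0.35 with slide as a block, 0.54 within the slide), but -0.30 under median scaling and -2.75 scaled to the spike-ins, and its camera adjusted p of 0.0335 became an adjusted p of 0.413 with an estimated correlation. Of 20 histone genes 5 rose and 8 fell (6 and 8 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.146), with a median of 0.03, which was -0.59 under median scaling and -0.16 under quantile normalization, and a mean of -0.35.

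Of 27 p53 target genes 14 rose, 2 fell and 11 did not pass, the same adjusted over the list alone, among them BTG2 (9.69-fold, adjusted p = 9.02e-07), the pro-apoptotic gene BBC3 (4.34-fold, adjusted p = 8.44e-06) and SESN2 (4.02-fold, adjusted p = 2.23e-05). Their median was 0.93 (0.99 with slide as a block, 0.90 within the slide, -2.15 scaled to the spike-ins), with a camera adjusted p of 0.00233 and an adjusted p of 0.275 with an estimated correlation. Of 39 MYC-activated genes 0 rose and 31 fell (0 and 32 adjusted over the list alone), among them the ribosome biogenesis genes RRS1 (3.17-fold lower, adjusted p = 7.49e-07) and POLR1B (2.93-fold lower, adjusted p = 3.32e-08). TFAP4 was at least 1.44-fold lower (adjusted p = 4.33e-07), which turned under normexp and with subtracted background plus 50. The median of the MYC-activated list was -0.67 (-0.57 both with slide as a block and within the slide, -3.75 scaled to the spike-ins), with a camera adjusted p of 7.42e-11 and an adjusted p of 0.196 with an estimated correlation. Of 19 MYC-repressed genes 14 rose and 1 fell, the same adjusted over the list alone, with ZFP36L1 9.84-fold higher (adjusted p = 0.000261). Their median was 1.06 (0.96 with slide as a block, 1.13 within the slide, -2.02 scaled to the spike-ins), with a camera adjusted p of 0.00261 and an adjusted p of 0.275 with an estimated correlation. Of 12 MYC network genes 5 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.662), with MYCL 5.25-fold higher (adjusted p = 1.3e-06). Scaled to the spike-ins CCNE2, E2F2, BBC3, SESN2 and MYCL went the other way (log2 -0.40, -1.05, -0.96, -1.07 and -0.68), while BTG2 and ZFP36L1 had 0.20 and 0.23.

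Early response, inflammatory and heat shock genes changed in different directions. Of 16 immediate early genes 15 rose and 0 fell, of 22 NF-kB and inflammatory genes 15 rose and 0 fell and of 26 interferon response genes 14 rose and 0 fell, each the same adjusted over the list alone. The interleukin gene IL1B was 9.82-fold higher (adjusted p = 1.15e-06), BIRC3 5.55-fold (adjusted p = 0.00605, and 0.0519 with slide as a block) and IFI44 6.90-fold (adjusted p = 0.000823), or log2 0.22, -0.60 and -0.29 scaled to the spike-ins. The 3 medians were 1.84, 1.66 and 1.06, or 1.79, 1.44 and 0.97 with slide as a block and 1.62, 1.64 and 1.01 within the slide, but -1.23, -1.42 and -2.01 scaled to the spike-ins. Camera gave adjusted p-values of 2.03e-06, 0.00146 and 0.0164, which became adjusted p = 0.196, 0.432 and 0.685 with an estimated correlation, and the interferon list had an adjusted p of 0.0584 with slide as a block. Of 12 heat shock genes 0 rose and 8 fell, the same adjusted over the list alone, with the chaperone genes HSPA1A 3.91-fold lower (adjusted p = 6.24e-07) and HSPA8 3.32-fold lower (adjusted p = 3.21e-07). Their median was -0.62 (-0.58 with slide as a block, -0.59 within the slide, -3.69 scaled to the spike-ins), with a camera adjusted p of 0.000383 and an adjusted p of 0.24 with an estimated correlation.

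Maturation genes changed in both directions. Of 18 mature neutrophil genes 10 rose, 2 fell and 6 did not pass, the same adjusted over the list alone, with S100A8 5.71-fold higher (adjusted p = 0.000437) and ITGAM 2.41-fold (adjusted p = 3.31e-06), both negative scaled to the spike-ins (log2 -0.56 and -1.81). Their median was 1.25 (1.15 with slide as a block, 1.11 within the slide, -1.82 scaled to the spike-ins), with a camera adjusted p of 0.00731 and an adjusted p of 0.297 with an estimated correlation. Of 14 primary granule genes 1 rose and 12 fell, the same adjusted over the list alone, including the granule protein genes PRTN3 (5.38-fold lower, adjusted p = 4.01e-07) and RNASE3 (4.23-fold lower, adjusted p = 1.56e-07). Their median was -1.08 (-0.91 with slide as a block, -0.67 within the slide, -4.16 scaled to the spike-ins), with a camera adjusted p of 2.23e-06 and an adjusted p of 0.275 with an estimated correlation. Of 18 retinoid genes 7 rose and 2 fell and of 23 RA-responsive genes 12 rose and 3 fell, the same adjusted over the list alone (medians 0.39 and 0.53, but -0.23 and -0.09 under median scaling and -2.68 and -2.54 scaled to the spike-ins). Neither list passed camera (adjusted p = 0.639 and 0.171). DHRS3 (log2 -0.08, adjusted p = 0.752) and CEBPE (log2 -0.26, adjusted p = 0.291) were not called but were called lower under median scaling. CYP26A1 was 1.82-fold higher (adjusted p = 0.03), a call that ended with a smaller change under quantile normalization (log2 0.28, adjusted p = 0.531) and with no smaller change when slide was a block (log2 0.92, adjusted p = 0.0753), and that turned to log2 -2.21 scaled to the spike-ins. The CYP26A1 call also ended without RA replicate 1 (adjusted p = 0.0666) or 3 (0.0798) and without AraC replicate 1 (0.0686) or 3 (0.142). Under normexp the calls of CYP26A1, ACP7, MYCL, S100A8 and PRDM12 ended (adjusted p = 0.289, 0.136, 0.0874, 0.0723 and 0.85). Rises and falls in the lists left, none of which passed camera, were 9 and 4 of 17 unfolded protein response genes, 10 and 4 of 26 apoptosis regulators and 4 and 9 of 38 ribosomal protein genes, where RPS16 was 2.00-fold lower (adjusted p = 0.000875). Adjusted over the list alone they were 9 and 4, 10 and 4, and 4 and 8.

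Some markers of other cell types were also called on the AraC arrays. Rises and falls were 7 and 1 of 10 erythroid and megakaryocyte genes, 5 and 1 of 11 lymphoid genes, 4 and 1 of 10 monocyte genes and 1 and 0 of 3 fibroblast genes (7 and 1, 6 and 1, 6 and 1, and 2 and 0 adjusted over the list alone). The haemoglobin gene HBA2 was 38.4-fold higher (adjusted p = 3.76e-08, and log2 2.19 scaled to the spike-ins), the costimulator gene CD86 22.5-fold (adjusted p = 3.84e-05, log2 1.42) and NKG7 3.24-fold (adjusted p = 4.73e-07, log2 -1.38). The 4 medians were 1.19, 0.72, 0.72 and 0.55, all negative scaled to the spike-ins (-1.88, -2.36, -2.35 and -2.52), with the fibroblast median also negative under median scaling (-0.07), and camera passed none of them.

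**Figure D4:**
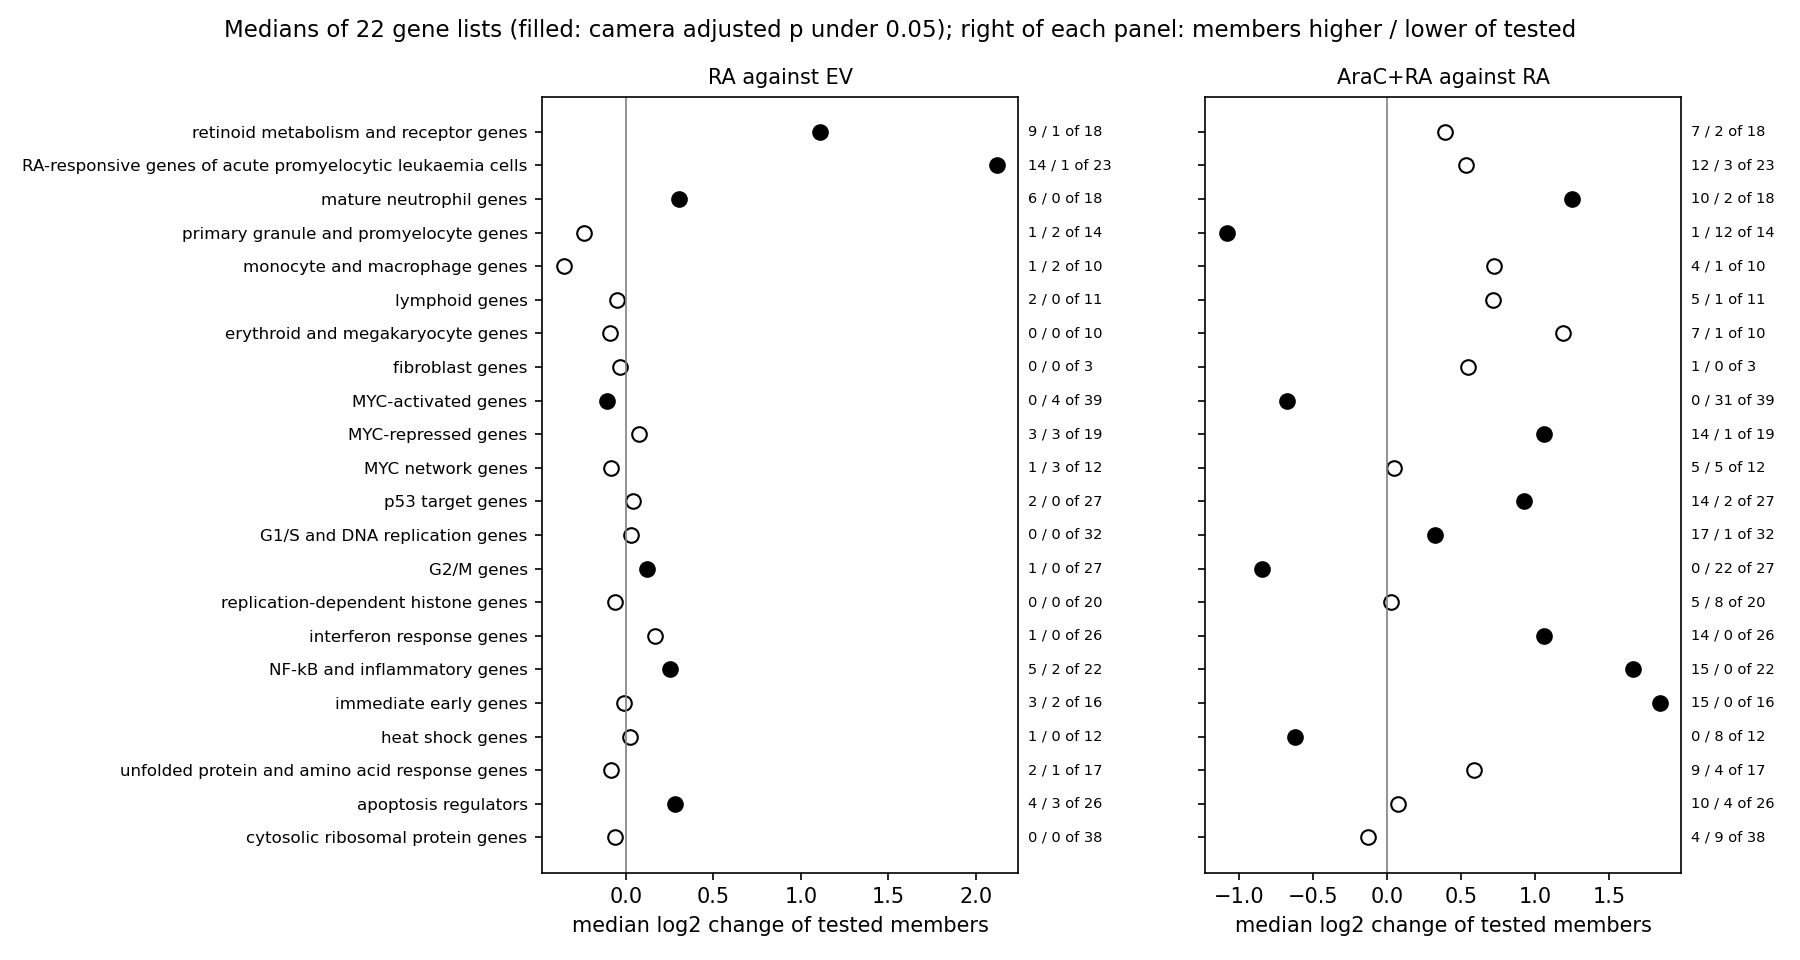
Median log2 change of the tested members of 22 gene lists for RA against EV (left) and AraC with RA against RA (right), filled where camera with the preset correlation gave an adjusted p below 0.05, with the numbers of members higher and lower of those tested at the right of each panel. For AraC the G2/M median was -0.84 and that of immediate early genes 1.84, and every median on the right was negative when scaled to the spike-ins; on the left that scaling turned several small negative medians positive, the MYC-activated one from -0.11 to 0.03.

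In all, limma called 10472 of 19763 genes with AraC, 6317 higher and 4155 lower, and 4752 by at least 2-fold (3934 higher, 818 lower). The balance depended on the scaling, with 4281 higher and 5619 lower under quantile normalization, 2916 and 8994 under median scaling, 4053 and 5407 in the authors' deposited value table, and 139 and 18861 scaled to the spike-ins. Subtracted background plus 50 gave 11204 higher and 3665 lower, no filter on dim probes 11437 and 4140, and normexp 1913 and 2201. With slide as a block 5328 were higher and 3587 lower. The groups did not overlap for 9211 of the called genes, and for 10024 of all genes against 1129 (5.71%) that chance gives.

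The last comparisons set each RA-treated group against EV. With MycD and RA, ID1 was 175-fold higher (log2 7.45, SE 0.14, n = 4 and 4, adjusted p = 1.28e-15), DHRS3 61.8-fold (adjusted p = 1.83e-12) and CYP26A1 8.02-fold, and MYC was 2.45-fold lower (adjusted p = 1.09e-05). With MycA and RA, ID1 was 164-fold higher (log2 7.35), DHRS3 60.6-fold and CYP26A1 8.50-fold, and MYC was 2.33-fold lower (adjusted p = 2.22e-05). ANGPTL4 was 138-fold and 121-fold higher, TGM2 rose by log2 6.89 and 6.58, HIC1 by 5.32 and 5.24, and RHBDL3 was at least 26.0-fold and 26.6-fold higher. The TGM2 probe was above background on 1 of 4 EV arrays, which leaves the size of its rise uncertain. CEBPE rose by log2 1.18 and 1.06 and ITGAM by 0.67 and 0.77, while CDKN1A had 0.10 and 0.11 (adjusted p = 0.956 and 0.997). IRS1 fell by log2 2.82 and 2.69, RAB7B fell by 2.77 and 2.90, and NOG fell by 2.72 and 2.53. CYP27C1 was at least 3.13-fold lower with MycD and at least 2.92-fold lower with MycA, and TGFBI at least 2.62-fold and 2.44-fold lower. STYK1 fell by log2 2.33 with MycD, and FST was at least 2.42-fold lower with MycA. With subtracted background plus 50, TGFBI was no longer called with MycD (limma adjusted p = 0.18). Nor were CYP27C1, FST and TGFBI with MycA (limma adjusted p = 0.167, 0.216 and 0.337). Against EV, normexp turned the direction of CYP27C1, FST and TGFBI with MycA and ended the calls of CYP26A1 with MycD and MycA (adjusted p = 0.381 and 0.0998), of CYP27C1, TGFBI, STYK1 and ITGAM with MycD (adjusted p = 1, 1, 0.116 and 0.104) and of IRS1 with MycA (adjusted p = 0.0776).

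Limma called 1416 genes with MycD (846 higher, 570 lower) and 1240 with MycA (719 higher, 521 lower). Scaled to the spike-ins the numbers were 630 higher and 222 lower, and 569 higher and 203 lower. With slide as a block they were 1007 and 1061 genes in all.

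With AraC and RA, ANGPTL4 was 863-fold higher than in EV (log2 9.75), RHBDL3 at least 61.6-fold and the lysosomal reductase gene IFI30 145-fold. The granzyme inhibitor gene SERPINB9 and TGM2 were also called higher, but their probes were above background on 1 of 4 EV arrays, which leaves the size of the rise uncertain. CDKN1A was 12.1-fold higher, CYP26A1 17.7-fold, DHRS3 53.2-fold and ITGAM 4.23-fold (limma adjusted p = 1.04e-06, 2.24e-08, 4.59e-12 and 1.1e-08). CEBPE had a log2 change of 0.90 (adjusted p = 0.00132), which was no longer called under median scaling. Scaled to the spike-ins, the log2 changes were 6.82 for ANGPTL4, 4.24 for IFI30, 4.20 for SERPINB9, 4.16 for TGM2, 1.21 for CYP26A1, 2.80 for DHRS3, 0.66 for CDKN1A, -0.86 for ITGAM and -2.04 for CEBPE. MYC was 7.50-fold lower (log2 -2.91, adjusted p = 5.69e-10) and PRDM12 at least 5.11-fold lower. The PRDM12 call ended under normexp (log2 -0.035, limma adjusted p = 0.947) and with subtracted background plus 50 (log2 -0.025, limma adjusted p = 0.908). H1-3 fell by log2 3.40, KIRREL3 fell by 3.24, the growth factor gene HGF fell by 3.00, MRGPRF fell by 2.98 and the chemokine receptor gene CCR2 fell by 2.95. The other probe of KIRREL3 fell by 0.82, and that of MRGPRF went the other way by 1.25. In all 10887 genes were called (6399 higher, 4488 lower). They were 4418 higher and 5922 lower under quantile normalization, 3009 and 8989 under median scaling, 4229 and 5726 in the authors' deposited value table, 11198 and 3955 with subtracted background plus 50, 11298 and 4461 with no filter on dim probes, and 213 and 18626 scaled to the spike-ins. Slide as a block gave 9681 genes.

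The RA response was then compared between groups. Of the genes called for RA against EV, 658 were also higher and 440 also lower with MycD (30.7 and 15.5 for independent lists), and 656 and 445 with MycA (26.1 and 14.2), with 0 in opposite directions in both. With AraC 619 were also higher and 282 also lower (232 and 122 for independent lists), and 116 were called in opposite directions. The AraC overlap depended on the scaling, with 541 higher, 282 lower and 90 opposite under quantile normalization, 418, 280 and 70 under median scaling, and 84, 180 and 404 scaled to the spike-ins. Unchanged groups simulated from the spread of the arrays without AraC, 4 arrays each with 4 control arrays in common, shared 0 called genes. These simulated groups do not match the 3 AraC arrays in size, and the spread of those arrays was not used. The correlation of log2 changes across genes, which are not independent replicates, was 0.874 with MycD, 0.900 with MycA and 0.362 with AraC, against 0.499 for simulated unchanged groups and 0.581, 0.586 and 0.256 with the EV arrays split 2 and 2. Genes responding to RA on 2 EV and 2 RA arrays were measured on the others, where the change from EV with MycD and RA was 1.03 of that with RA alone (median over splits, range 0.958 to 1.91). It was 1.00 with MycA (0.937 to 1.84) and 1.04 with AraC (0.991 to 1.71), over 25 of 36 splits that selected at least 5 genes. These values were 1.03 with MycD, 1.01 with MycA and 0.304 with AraC when scaled to the spike-ins, a choice made after seeing the data. No group held Myc or AraC without RA. Each share therefore includes any effect of Myc or AraC itself on these genes, and does not isolate the RA response in those cells.

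The changes that MycD, MycA and AraC brought over RA were also set side by side. CYP27C1 was the only gene called lower with both Myc forms, against 0 shared calls in simulations. Across genes the log2 changes with MycD and MycA correlated at 0.504, against 0.498 for simulated unchanged groups with control arrays in common and -0.153 with the RA arrays split 2 and 2. These simulations, too, drew on the spread of the arrays without AraC. The covariance was 0.0228 against a simulated 0.0437. Between MycD and AraC the correlation was 0.308 (simulated 0.462, split 0.109) and the covariance 0.0706 (simulated 0.0429). Between MycA and AraC the correlation was 0.254 (simulated 0.434, split 0.0494) and the covariance 0.0502 (simulated 0.0387).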

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

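Of the tests below, those on probes brighter before scaling and on RNA degradation were fixed before their results were seen, and all the others were chosen only after.

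On the AraC arrays 2-fold rises (3934) far outnumbered 2-fold falls (818), while control RNA spiked into the labelling was 2.21-fold brighter than on the RA arrays. One technical explanation is that dim probes were held up by background while brighter probes lost signal. Genes were ranked by their signal on the RA arrays into 3 equal sets. In the brightest set the balance did turn, to 0.693 rises per fall (311 and 449). However, the scaling fixes each array at an upper percentile of its signal, which tends to keep bright genes near no change. The ranking also used the RA arrays, themselves part of the comparison. The turn therefore cannot tell how much of the excess of rises background on dim probes accounts for. Background on dim probes does not account for every rise in array signal. Of the 2-fold rises, 10.4% (411 genes, among them CDKN1A, CXCL8, EGR3, JUN and HBA2) were brighter on every AraC than on every RA array before any scaling. The spike-ins were brighter there too, so an unscaled rise of their size need not be a rise of the transcript. Scaled to the spike-ins, 139 of all tested genes were called higher. Degraded RNA is argued against for 1372 transcripts with 2 probes at least 1000 bases apart, both above background on every array. The log2 change of the probe farther from the 3′ end minus that of the nearer probe had a median of -0.0302. Its 95% interval, -0.0576 to 0.00545, is over transcripts and not over arrays. For RA against EV that median was 0.0308. Transcripts with a probe that fell to background on an AraC array were left out, so the pairs cannot decide about those. Less messenger RNA in AraC-treated cells, less labelled RNA on the arrays and another amount of spike-in stay open and untested.

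A probe of ESR1, the oestrogen receptor gene whose product gives the ER tag its name, was well above background on all 8 MycD and MycA arrays and on no other array. It was at least 3.02-fold higher with MycD and at least 2.10-fold higher with MycA than with RA, though limma over all probes did not call it (adjusted p = 0.835 and 1). Its place is chromosome 6, 152265523 to 152265582 in hg19, and this probe was singled out after its values were seen. The scaled log2 signals themselves overlapped, with 3.02 on MycA replicate 1, well above background, and 3.05 on EV replicate 4, not so. The checks of chance and slide below use only whether a probe was above background. Chance among many probes is argued against, since 159 of 12870 splits of the 16 arrays without AraC had a probe with such a pattern. The same holds for the probe of CYP27C1, which among those 16 was above background on the 8 EV and RA arrays alone. That probe was also above background on 1 AraC array. Slide is argued against for the ESR1 probe, since its pattern held on all 7 slides, each with both kinds of array. A transcript of the vector's tag is a candidate explanation, but the labels also give the empty vector the tag, and transcription of the ESR1 gene itself cannot be told apart from it, because the probe nearest the 3′ end was above background on 1 of the 8 Myc arrays, while a probe near the 5′ end, above background on every array, had log2 changes of 0.03 with MycD and 0.01 with MycA over RA (adjusted p = 1) and so gave no sign of it.

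Interferon response genes averaged log2 0.64 higher with MycD than with MycA. The difference could be chance between arrays (exact permutation p = 0.114, n = 4 and 4, two-sided). Slide cannot be told apart from it, since the median of the list was still 0.343 with slide as a block but slide-adjusted array means gave an exact permutation p of 0.286. Over the 16 arrays without AraC the list mean followed the experiment number of the descriptions (permutation p = 0.00801, permuted within groups), which may be a shared difference between cultures, with a mean of 0.98 ± 0.16 in experiment 1 (SD, n = 4) against 0.21 ± 0.65, -0.17 ± 0.37 and 0.10 ± 0.32 for experiments 4, 5 and 7. Within experiments MycD was above MycA in 4 of 4 (0.28 to 0.94, exact sign-flip permutation p = 0.125, the smallest possible), but above RA in 3 of 4 (-0.05 to 1.22, sign-flip permutation p = 0.25, and exact permutation p = 0.2 over all arrays), so an effect of MycD on these genes stays open.

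Other splits of the same arrays into groups of the same sizes were run for each comparison, 35 splits each. As many genes as in the real split were called by 1 split (the real one) for RA against EV (1255 genes, highest other 6), AraC against RA (10472, highest other 6379), MycD against EV (1416, highest other 2), MycA against EV (1240, highest other 161) and AraC against EV (10887, highest other 7865). A chance split is argued against for these but not excluded, since 1 of 35 is the smallest share possible. The other splits also hold the real difference in their spread, which lowers their counts. For MycA against RA 2 of 35 splits called as many, the real one with 1 gene and another with 6, so chance is not excluded for that number of calls. Between the Myc forms all 35 splits called 0, the real one included, so there was no call to test. For MycD against RA 1 split, the real one, called as many (1 gene, highest other 0). Counts this small do not test the gene itself, CYP27C1 in both comparisons, whose probe is weighed above. Some of the higher other splits went with slides. The split with 161 genes set the arrays of slides 4 and 7 against the rest, and that with 6 genes for RA against EV the arrays of slides 4 and 5, which were also those of experiments 4 and 5. MycA against EV had 1061 and RA against EV 957 genes with slide as a block, and MycA against RA 1. The splits with 6379 and 7865 genes left all AraC arrays together with a single RA or EV array.

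A single array lay far from the other 3 of its group in 21 of 440 sets of values checked, against 22 that chance gives (about 1 in 20). MycD replicate 2 had 73.7% of spots well above background (others 78.8% to 79.6%), and its log2 levels of BIRC3 (9.57) and CCR2 (7.93) were the lowest of the group. MycA replicate 2 had the highest mean of RA-responsive genes (2.18, others 1.70 to 1.74), and its log2 levels of ITGAM (9.24), NCF1 (15.61) and TGM2 (10.39, others 8.95 to 9.06) were also the highest. MycA replicate 4 was lowest for EGR3 (2.38) and highest for H1-3 (13.56) and TFAP4 (5.90), and MycA replicate 1 was lowest for HBA2 (4.21). RA replicate 4 had the lowest mean of MYC-activated genes (-0.35, others -0.15 to -0.11) and of MYB (14.08) and the highest H1-3 (13.60), and RA replicate 2 had the highest HBA2 (6.04). EV replicate 4 was highest for CEBPE (14.72), FST (4.49), PRTN3 (12.43) and RNASE3 (11.22), EV replicate 3 lowest for SLC22A7 (7.41) and EV replicate 1 lowest for STYK1 (7.08).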

How the results depend on the processing

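Spike-in scaling, subtracted background plus 50 and the fit without the AraC arrays were chosen only after the data were seen, the other alternatives before. The cause was not tested for any change below unless stated. Scaled to the spike-ins, 775 genes were called for RA against EV, 19000 for AraC against RA, 852, 772 and 18839 for MycD, MycA and AraC against EV. Under normexp, whose fitted background was raised on RA replicate 4 and MycA replicate 3, the numbers were 517 for RA against EV, 0 for MycD and 0 for MycA against RA, 4114 for AraC against RA, and 545 and 484 for MycD and MycA against EV. Normexp turned TGFBI for RA against EV (log2 0.53), TFAP4 for AraC against RA (0.24), and CYP27C1, FST and TGFBI for MycA against EV (0.048, 0.086 and 0.095). Subtracted background plus 50 called 0 genes for MycD and 0 for MycA against RA, and turned PRDM12 (0.57) and TFAP4 (0.99) for AraC against RA. The authors' table called 0 and 0 for the Myc comparisons with RA, as did testing only probes above background on all arrays, which leaves CYP27C1 out. A 2-fold minimum, which by construction keeps fewer genes, gave 520 for RA against EV, 4752 for AraC against RA, and 559, 517 and 5137 for MycD, MycA and AraC against EV.

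Camera's 27 list calls fell to 3 with an estimated correlation, and fry, which asks whether a list moves and not whether it moves more than others, gave 26 and called 0 in the Myc comparisons. These were partly other lists. For RA against EV fry called MYC network genes lower (adjusted p = 0.000678) and MYC-repressed and lymphoid genes higher (0.0149 and 0.0304). It did not call MYC-activated, G2/M and NF-kB genes (fry adjusted p = 0.0998, 0.0806 and 0.0503). For AraC against RA it also called lists that camera did not. The share of the RA response with AraC moved to 0.304 scaled to the spike-ins, 1.10 under normexp and 1.09 with genes chosen and measured on the same arrays. With each array left out in turn, calls ranged from 1006 to 1126 for RA against EV, 9096 to 10026.0 for AraC against RA, 1139 to 1306 for MycD against EV, 963 to 1163 for MycA against EV and 9678 to 10779 for AraC against EV. They stayed at 1 for MycD against RA and 0 between the Myc forms, where every alternative also called 0. They ranged from 1 to 2 for MycA against RA, where LOC338864 (named after its values were seen) was also lower without MycA replicate 3 (adjusted p = 0.0277). Shares of the RA response stayed between 0.978 (MycA) and 1.05 (AraC).

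With the experiment number of the descriptions as a replicate block, 1485 genes were called for RA against EV, 1 for MycD and 1 for MycA against RA, 10869 for AraC against RA, 0 between the Myc forms, and 1737, 1503 and 11158 against EV, with 32 list calls. The 5 lists that passed only with this replicate block were interferon response genes for RA against EV (median 0.17, adjusted p = 0.0404, against 0.11 without it) and for MycA against RA (-0.12, adjusted p = 0.025), RA-responsive genes for AraC against RA (0.60, adjusted p = 0.0442) and for MycD against MycA (0.12, adjusted p = 0.0161), and heat shock genes for MycD against MycA (-0.09, adjusted p = 0.0161). With the title number as a replicate block they were 1039, 1, 1, 9889, 0, 1205, 1067 and 10355. These numbers were shared but over all genes not shown to pair cultures, although the interferon list means followed the experiment number, as given above. Deviations of same-numbered arrays correlated by -0.011 on average for experiment numbers (14 of 36 pairs above 0.1, 6 of 19 arrays closest to their own number) and -0.065 for title numbers (10 of 36, 4 of 19). For arrays of the same slide the mean was 0.316 (17 of 18 pairs above 0.1, 7 of 19 arrays closest to their own slide), against -0.045 for other pairs. Arrays of a slide thus shared deviations, and the main fit had no term for slide, experiment number or title number. Spike-in scaling and the 2-fold minimum were left out of the following count. Of the log2 changes of named genes under the other alternatives, 809 of 823 for RA against EV and 981 of 1001 for AraC against RA kept their side of the threshold. Those that stayed called also kept their direction, while the direction of those that stayed uncalled was not checked. For each Myc form against RA the count was 157 of 160, mostly of genes that stayed uncalled, since only CYP27C1 was called there. Spike-in scaling turned the direction of a number of AraC rises, as given above. No call of a named gene was lost or gained with either replicate block.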

Other observations

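The values and checks in this part were chosen only after the values were seen. Small non-coding RNAs, mostly not polyadenylated, held some of the largest rises with AraC over RA. The spliceosomal RNA genes RNU2-2 and RNVU1-18 were 114-fold and 40.6-fold higher (spike-in-scaled log2 3.76 and 2.27), RN7SK, which holds back the elongation factor P-TEFb, 35.9-fold (2.09), and RNU12 14.4-fold (0.77). RN7SL1, of the signal recognition particle, was 11.3-fold higher (0.42), the RNase P RNA RPPH1 10.8-fold (0.36) and RMRP 6.02-fold (-0.48). Of 55 tested small RNA genes limma called 23 higher and 13 lower, or 22 and 25 under quantile normalization and 21 and 22 under median scaling. Scaled to the spike-ins 4 were higher and 47 lower.

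To see whether brightness alone set the AraC list medians, each was placed among 10000 random lists of the same size matched on brightness in RA. The medians of interferon, NF-kB, immediate early, MYC-repressed, neutrophil, G1/S and unfolded protein response genes lay above all of them, and those of RA-responsive and p53 target genes at percentile 99.99. Primary granule and G2/M genes lay below all of them and MYC-activated genes at 0.01. Heat shock genes lay at 3.03, erythroid genes at 96.0 and lymphoid genes at 95.5. These and the medians of monocyte (93.7), apoptosis (92.9), retinoid (85.7), ribosomal protein (84.2), MYC network (83.3), histone (59.3) and fibroblast genes (44.8) lay inside the middle 95% of the random lists. The percentiles describe these arrays and are not p-values.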
